A study of Arabidopsis thaliana with 16 samples.

How the data were processed

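PIP-seq was run on nuclei of root hair and nonhair cells, each treated with ssRNase (RNase ONE) or dsRNase (RNase V1), with proteins bound or digested, in 2 replicates each, 16 samples in all. Each lysate was split between the RNases, per the labels' protocols. Reads were processed with cutadapt 1.2.1 and TopHat2 2.0.10 on the TAIR10 build, per the submitters' processing notes, which give these tools no order or role. PPS carry a CSAR score per site, which the authors deposited at a false discovery rate of 5%, per the names of the lists, as 8 lists called per cell type, replicate and RNase and 2 lists merged over replicates and RNases. How reads of the libraries with and without protein entered the caller is not given in the sources used here. The deposited structure score has 1 value per base of each transcript, pooled over both replicates, for spliced and unspliced transcripts. How that score was made is not given in the sources used here.

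The sample descriptions of nonhair replicate 1 with ssRNase and nonhair replicate 2 with dsRNase name each other's PPS list, against their titles. The merged nonhair list names the RNase of every site, and all 41402 PPS of the disputed lists stand there under the RNase of their title, so titles were followed. The exchange was kept as an alternative. The merged lists also carry internal replicate numbers: 3 and 4 for hair and for nonhair with dsRNase, but 5 and 6 for nonhair with ssRNase. The nonhair ssRNase libraries may therefore come from another preparation, which the labels do not say, and no fit can separate that from cell type within ssRNase.

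Gene models came from the RefSeq annotation of TAIR10.1. Of 16243 coding models in the structure files, 98.4% had the same coding start and end in it, and nuclear coordinates were used as deposited. Chloroplast coordinates were used too; no coding model checked them, and their highest position, 154312, lies within the 154478 bases of the reference. The mitochondrial genome was left out of regions, genes, structure scores and motifs, because no coding model could check its coordinates and its sequence may not be the one of TAIR10. Mitochondrial PPS remain in the numbers, lengths, covered length and overlaps of PPS. Coordinates are counted from 1.

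The structure score was decoded to see what depth lies behind it. Each value matched g(a) - g(k × b), where g(x) is log2(x + sqrt(x × x + 1)), a and b are whole read numbers of a first and a second library, and k is 3.5 in hair and 3.56 in nonhair; a grid of scales was searched for the value that put most bases on whole reads. At these scales 63.7% of hair and 47.0% of nonhair bases lay on values of up to 5 reads in each library, against 63.0% and 45.8% at the next highest scale and a median of 39.6% and 31.4% over the scales searched. Every value was given the fewest reads that match it. Per transcript these reads per base were summed over bases, so a read may count at more than 1 base. Reads and CPM of transcripts given below are such sums of depth, not numbers of reads. With more reads almost any value at 2 decimals can be matched, so that all scored bases matched is no check, and recovered reads are approximate; on simulated scores of lower depth a share of 0.992 of bases gave back the reads drawn. Mean depth was 6.17 reads per base in the first and 1.60 in the second library for hair, and 11.2 and 2.52 for nonhair. Many bases had almost no reads: 16.9% of hair and 10.7% of nonhair bases stood at 1 read against 0, a score of 1.27. The mean score was 0.752 over 23514999 bases in hair and 1.02 over 27979230 in nonhair. To find its direction, 1000 windows of 200 nt were folded with ViennaRNA 2.7.2. Bases predicted paired had a mean score of 0.730 against 0.674 unpaired in hair and 1.07 against 0.991 in nonhair, with a median r within windows of 0.00258 and 0.0201. Across 7081 genes, which are not replicates, hair minus nonhair differences in PPS coverage had a Spearman rho with those in reads of the first and second library of 0.268 and -0.122 with ssRNase and 0.232 and 0.319 with dsRNase. These values lean toward the first library as the ssRNase one, but rest on PPS that may have been called against the same libraries, so the direction was left unsettled.

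PPS were compared by overlap of at least 1 base on the same strand. Shares of PPS bases per region were taken with coding sequence before UTRs and introns. Cell types were compared by a two-sided exact permutation of cell type within RNase (36 assignments), and RNases by a two-sided exact sign-flip permutation over preparations (16 assignments). The permutation of cell type treats the 2 lists of a preparation as independent, although the lysate was split between the RNases. Preparations were taken as lists of the same cell type and replicate number, which for nonhair the internal numbers leave open. Gene level values are PPS-covered bases per gene and list, tested with limma 3.58.1 in R 4.3.3 on log2(bases + 10), with RNase as a term and preparation as a correlated block (duplicateCorrelation, statmod 1.5.0), for 10196 of 12218 genes with a PPS, those with one in at least 2 of 8 lists. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The estimated correlation within preparations was -0.311, from a fit without a term for cell type differences that depend on the RNase. It therefore does not by itself measure how alike lists of a preparation were. With the mean of each cell type and RNase removed, lists of the same replicate number correlated at 0.0172 in hair and -0.00897 in nonhair. Without the negative correlation fewer genes were called, 71 against 112 for hair and 46 against 66 for nonhair. Gene lists were tested with camera (preset correlation 0.01, and estimated), adjusted over 15 lists. The estimated correlation was used on the fit as reported alone, and all other settings used the preset one. Of these, 8 were fixed with their members before the data were examined: cell fate, root hair growth, phosphate starvation, RNA-binding, photosynthesis, other root cell types, housekeeping and nuclear tag genes. The other groups (ribosomal proteins, chloroplast genes, tRNA, rRNA, snRNA, snoRNA and lncRNA) were named before and took their members from the annotation. Transcripts were compared by mean structure score over at least 200 bases scored in both cell types, and lists by their percentile among 10000 random lists matched on mean score. Motifs, 10 in number, were counted against 10 shuffled positions per PPS in the same region kind of the same gene. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.

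Genes named in the text are the 10 largest differences in each direction among genes past the test whose 4 lists of one cell type all lie above those of the other. To these were added every cell fate gene with a PPS in at least 2 lists, ADF8, GL2, GRP7, GRP8, SE and CP29A, and the 2 genes of smallest p of every other list. For structure they are the 5 largest differences in each direction among transcripts with at least 500 bases scored in both.

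The gene level fit was tested on simulated data, 4 runs of 200 changed genes. In the planned simulation, with Poisson numbers of PPS, it recovered 0, 0 and 0.379% of 2-, 4- and 8-fold changes over 9612 genes, with 0 false calls. In a second one, added after that and built from sites with their own detection rates (8691 genes), it recovered 1%, 8.5%, 20.5% and 52.5% of 2-, 4-, 8- and 100-fold changes, with 2.25 false calls per run. Most changes of up to 8-fold would therefore be missed. Neither simulation held an effect of preparation, a cell type difference that depends on the RNase, or nonhair ssRNase lists of another preparation. The false calls therefore do not carry over to the real lists.

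Alternatives covered the score threshold of PPS, overlap rules, pseudocount, filters, scaling, the correlation of preparations, a replicate block, RNases taken alone, each replicate left out, flank and window lengths, the spliced or unspliced file, and motif backgrounds. Chosen after seeing the data were dsRNase alone for lists, regions and motifs, the fit without nonhair ssRNase lists, a fit with these as preparations of their own, gene groups with a replicate left out under the filter of all lists, and reads recovered from the scores and summed. At codons the first form of the latter, a ratio per mRNA, gave the opposite sign at start codons; the summed form, with at least 5 reads per base, was settled on after its values were seen. A list of 22 cold and osmotic stress genes was also written after 8 of them had been seen.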

Results

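The root epidermis of Arabidopsis holds hair cells, which grow a tubular extension into the soil, and nonhair cells between them. Protein interaction profile sequencing (PIP-seq) was used to map where proteins cover RNA in the nuclei of each cell type and how the RNA is folded. Nuclei came from lines that tag nuclei under the ADF8 promoter (hair) or the GL2 promoter (nonhair) in the roots of 10-day seedlings, and were crosslinked with formaldehyde. Lysates were treated with an RNase that cuts single-stranded RNA (ssRNase) or double-stranded RNA (dsRNase), either with proteins still bound or after the proteins were digested away. The 16 samples make 2 replicates of each cell type, RNase and protein state. The values used here are 8 lists of protein protected sites (PPS, stretches of RNA shielded from RNase by protein), 1 per cell type, replicate and RNase, 2 merged lists and 4 files of structure scores pooled over replicates. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The read depth of the PPS libraries is unknown. The lists hold 22468 and 22436 PPS for hair with dsRNase, 13148 and 12828 for hair with ssRNase, 20295 and 29092 for nonhair with dsRNase, and 12310 and 11183 for nonhair with ssRNase.

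The first question was how much RNA each cell type showed under protein. Hair and nonhair nuclei had similar numbers of PPS, a mean of 17720 against 18220 over 4 lists each, and the exact permutation p within RNase was 1. PPS were 10.25 nt longer in hair by the mean of the list medians, 75 against 64.75 nt (exact permutation p = 0.111). The gap was 17 nt with ssRNase and 3.5 nt with dsRNase. Hair PPS covered 2160 ± 65.3 kb with dsRNase and 978 ± 60.9 kb with ssRNase, and nonhair PPS 2306 ± 706 kb and 640 ± 31.6 kb (SD, n = 2). The difference in covered length, 95.7 kb, had an exact permutation p of 0.778. Its sign turns without nonhair replicate 1 (-165 kb), and that of the number of PPS turns without nonhair replicate 2 (+1418). The smallest p that the 36 assignments of cell type within RNase allow is 0.0556, so no cell type difference tested this way can pass 0.05. The assignments move the 2 lists of the same cell type and replicate number separately, as if they were independent. If those lists were moved together, the smallest p would be larger.

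The RNases differed from each other more than the cell types did. Lists from dsRNase held 23573 PPS on average against 12367 from ssRNase, with median lengths of 84.75 against 55 nt. Protein-covered sequence reached 2233 kb against 809 kb. In all 4 pairs of lists with the same cell type and replicate number the dsRNase list held more and longer PPS. Internal numbers in the merged lists leave open whether the nonhair pairs share a preparation. Over these pairs the exact sign-flip permutation gave p = 0.125 for each measure, the smallest that its 16 sign assignments allow.

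Replicates shared more PPS than cell types did. Between replicates, 64.6% of PPS overlapped on the same strand with dsRNase and 53.3% with ssRNase. Between cell types it was 55.8% with dsRNase and 32.0% with ssRNase. The RNases of 1 replicate shared 47.3% and 42.4% in hair but 21.4% and 23.3% in nonhair. With either RNase every replicate pair shared more than every pair of cell types. All these overlaps were 1.91 to 2.85 times those of PPS shuffled within the same genes. In the merged lists, 72.8% of 34442 hair PPS overlapped a nonhair PPS, which leaves 9373 specific to hair. Of 44315 nonhair PPS, 59.0% overlapped a hair PPS, which leaves 18188. Few specific PPS recurred: 28.6% of those in hair and 24.6% in nonhair were in both replicates of an RNase. Most lay in genes bound in both cell types, 81.4% of hair-specific and 72.7% of nonhair-specific PPS. PPS were in 9536 genes in hair and 10932 in nonhair, with 8497 in common. There is 1 merged list per cell type, so these shares have no test.

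The next question was which parts of transcripts proteins covered. In hair nuclei more of the PPS sequence was coding, 71.4% against 55.2% in nonhair, a difference of 16.2 percentage points. Nonhair nuclei had more in introns, the spliced-out parts of pre-mRNA, 26.3% against 14.7%, and more in unannotated sequence, 5.02% against 3.01%. Coding sequence made up 77.0% of hair and 70.9% of nonhair PPS bases with dsRNase, and 65.9% and 39.5% ± 6.70 (SD, n = 2) with ssRNase. Introns held 12.3% and 18.8% with dsRNase and 17.0% and 33.9% ± 7.01 with ssRNase. For coding sequence, introns and unannotated sequence every hair list lay on 1 side of every nonhair list of the same RNase, and the exact permutation p was 0.0556, the smallest possible. For 3' UTRs the share was 0.595 points higher in hair (exact permutation p = 0.111), for pseudogenes 0.308 points (p = 0.167, exact), and for 5' UTRs -0.0444 points (p = 0.444, exact). With dsRNase alone the gap was 6.05 points for coding sequence and -6.45 for introns.

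**Figure D1:**
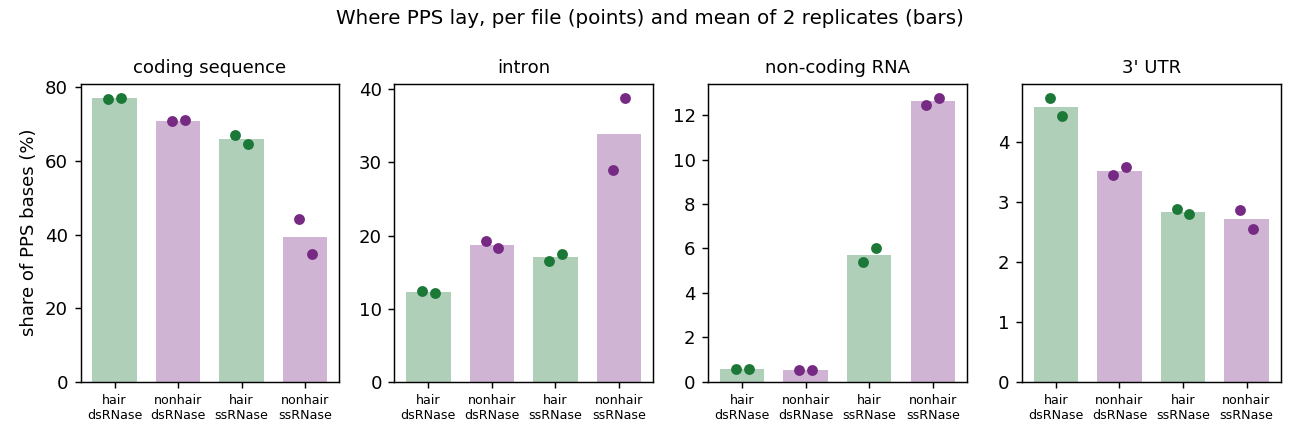
Share of PPS bases (%) in coding sequence, introns, non-coding RNA and 3' UTRs, with 1 point per list and bars for the mean of 2 replicates of each cell type and RNase. Nonhair with ssRNase stands apart, with 39.5% in coding sequence and 33.9% in introns.

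Small structured RNAs carried PPS almost only after ssRNase treatment, which spares paired RNA. Non-coding RNA held 5.70% of hair and 12.6% of nonhair PPS bases with ssRNase, against 0.564% and 0.525% with dsRNase. With ssRNase, transfer RNAs held 1.01% in hair and 4.31% in nonhair, small nucleolar RNAs, which guide rRNA modification, 2.04% and 3.58%, the snRNAs of the spliceosome 0.484% and 0.785%, and long non-coding RNAs 0.878% and 1.24%. These are shares of nuclear PPS bases, a smaller total in nonhair than in hair with ssRNase. With organelle PPS included, the covered totals were 640 against 978 kb. In bases, transfer RNAs had more under PPS in nonhair, 24204 and 26307 in its replicates against 8003 and 11085 in hair, and snoRNAs had 20542 and 21472 against 18608 and 19787. The snRNAs had nearly the same number, 4429 and 4771 against 4486 and 4599, and lncRNAs had fewer in nonhair, 6944 and 7566 against 7926 and 8595. Over both RNases the hair minus nonhair difference in share was -3.44 points for non-coding RNA (exact permutation p = 0.333). Relative to the length of such sequence in genes with a PPS, coverage of non-coding RNA with ssRNase was 6.23 times in hair and 14.3 times in nonhair, and that of coding sequence 1.46 times and 0.906 times. With dsRNase alone the non-coding difference turned to 0.0384 points. Between RNases, the shares of coding sequence, introns, non-coding RNA and 3' UTRs all differed in 1 direction in the 4 pairs (exact sign-flip permutation p = 0.125), and that of 5' UTRs did not (p = 0.75, exact).

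At the level of genes, the question was which transcripts were covered by protein in one cell type and not in the other. ADF8, an actin depolymerizing factor whose promoter marks hair nuclei, had PPS in all 4 hair lists (100.5 ± 42.0 covered bases, SD) and in no nonhair list. Its log2 difference was 3.38 with an SE of 0.23 (limma, adjusted p = 0.00161). GL2, the homeodomain regulator of nonhair fate whose promoter marks nonhair nuclei, had PPS in 2 of 4 nonhair lists and in no hair list, with a log2 difference of -1.48 that did not pass (limma, adjusted p = 0.177). Of 10196 genes tested, 112 had more PPS-covered bases in hair and 66 in nonhair, and 3070 had an unadjusted p under 0.05. Without the negative correlation estimated within preparations, 71 and 46 passed (limma). Differences are on the scale log2(covered bases + 10); for a gene listed at 0 in one cell type the value depends on the added 10 bases and is no fold change.

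Among the genes higher in hair were NET4A, an actin-binding protein of the NETWORKED family (log2 difference 4.96, SE 0.42), and WDL1, a microtubule-associated protein (4.38, SE 0.43). UMAMIT8, of a family of amino acid transporters, had 353 ± 144 covered bases in hair (SD, n = 4) and was listed at 0 in nonhair (TAIR10 chromosome 4, 9357844 to 9360239; log2 difference 5.07, SE 0.30, limma adjusted p = 0.00161). SQP2, a squalene epoxidase-like enzyme (4.78), and CT-BMY, a chloroplast beta-amylase that breaks down starch (4.61), were also higher. The gene furthest apart was AT3G60930, annotated as a pseudogene (chromosome 3, 22514027 to 22516871), with 428.5 ± 71.3 covered bases in hair and 0 in nonhair (log2 difference 5.44, SE 0.19, limma adjusted p = 0.000553). AT2G16890, AT1G73510, AT5G12410 and AT2G31560 followed with 4.84, 4.57, 4.48 and 4.23. Adjusted p over these 10 genes ran up to 0.0211. PPS coverage was not set against transcript amount in this test. In the first and second libraries without protein, CT-BMY had 188 and 200 CPM in hair against 11.2 and 109 in nonhair. CPM is read depth summed over bases, scaled to a common library total. Of 132 called genes with reads, 29.5% differed in the direction of the call by 2 times or more in either library.

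Among the genes higher in nonhair were GRF2, a 14-3-3 protein that binds phosphorylated partners, with 221 ± 39.6 covered bases in nonhair and 0 in hair (chromosome 1, 29461391 to 29463389; log2 difference -4.51, SE 0.20, limma adjusted p = 0.0011). HDA9, a histone deacetylase, stood at -3.75 (SE 0.32, adjusted p = 0.00244), CLPB4, a mitochondrial chaperone, at -3.81, and the kinases WNK1 and PTI1-4 at -4.06 and -3.84. SPX3, which acts in phosphate sensing, stood at -3.88 (limma adjusted p = 0.0392), a call that did not survive the loss of most single replicates. AT1G64610, AT3G54040, AT3G20370 and AT5G44910 stood at -4.08, -3.97, -3.93 and -3.79.

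**Figure D2:**
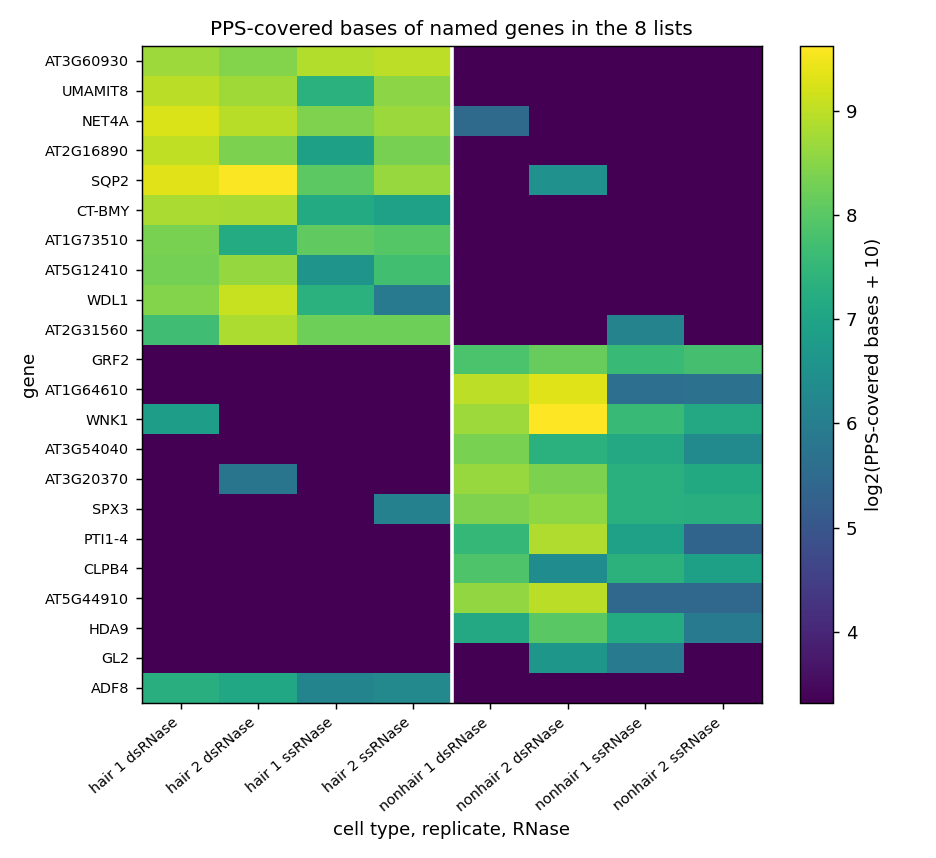
PPS-covered bases, as log2(bases + 10), of the 20 named genes, GL2 and ADF8 in the 8 lists, hair on the left and nonhair on the right of the white line. The first 10 genes and ADF8 are covered in all 4 hair lists, and the next 10 in all 4 nonhair lists.

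Gene counts rested on few samples. All 4 hair lists lay above all 4 nonhair lists for 237 genes and below for 87, where chance, taken as the mean over the 36 assignments of lists within RNase with the real ones included, gives 26.3 genes per direction and the highest of the other assignments 67. Within each RNase apart, hair lay above for 757 genes and below for 232, against a mean of 135 and a highest other of 550, so the nonhair number is below one that another assignment gives. With PPS in all 4 lists of one cell type and none of the other there were 58 genes for hair and 47 for nonhair. With dsRNase alone 390 and 510 genes passed (limma), of which 105 were among the 178. Without the nonhair ssRNase lists, which stand apart from the rest, 329 and 510 passed, a set tried after the data were seen. Leaving out hair replicate 1 gave 170 and 93 genes, nonhair replicate 1 gave 128 and 203, and nonhair replicate 2 gave 298 and 135. Some of the 20 genes lost their call this way (limma): SPX3 without hair replicate 1 (-3.18) or nonhair replicate 1 or 2 (-3.91, -3.84), WNK1 (-4.17, -3.95) and AT3G20370 (-3.82, -4.05) without nonhair replicate 1 or 2, SQP2 without hair replicate 1 or 2 (4.997, 4.56), AT2G31560 without hair replicate 1 or 2 (4.52, 3.94) or nonhair replicate 2 (3.53), AT5G44910 without hair replicate 1 (-3.79) or nonhair replicate 1 (-3.89), and PTI1-4 without nonhair replicate 1 (-3.80). At the stricter score threshold 13 of the 20 lost their call, HDA9 falling to -1.36 and CLPB4 to -1.64. With a pair of nonhair lists exchanged as the sample descriptions place them, 0 genes passed (limma, with 173 at an unadjusted p under 0.05). The merged list argues against that exchange. So do transfer RNA bases, 24204 in nonhair replicate 1 with ssRNase and 31 in nonhair replicate 2 with dsRNase by title. If titles hold, the exchange puts a list of each RNase among those of the other, so it does not measure how firm the calls are.

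Gene groups named before the data were examined were then compared; members of the ribosomal protein, chloroplast and non-coding RNA groups came from the annotation. Transfer RNA genes had more PPS coverage in nonhair: 399 of 417 tested had a negative log2 difference, with a median of -0.87 (camera, adjusted p = 1.1e-13; adjusted p = 0.661 with an estimated correlation). None passed on its own over all genes or over the list alone (limma, 0; 199 at an unadjusted p under 0.05). Genes of photosynthesis, which mark green tissue, were covered more in nonhair in 10 of 10 tested, median -1.87 (camera adjusted p = 0.000313; adjusted p = 0.661 with an estimated correlation). LHCA1 and LHCB1.3, proteins of the light-harvesting antenna, had differences of -2.86 and -2.55 (limma adjusted p = 0.0902 and 0.0978). No photosynthesis gene passed over all genes (limma, 0; 9 at an unadjusted p under 0.05), and 9 passed toward nonhair when adjusted over the list alone. Their coverage was 1637.5 ± 161 bases in nonhair with ssRNase against 68 ± 1.41 in hair (SD, n = 2). Of the libraries without protein, the second hair one held 3978 CPM of this group against 335 to 399 in the others. CPM here is read depth summed over bases and scaled to a common library total. Chloroplast-encoded genes had a median of -0.84 over 73 genes (camera adjusted p = 0.000313; adjusted p = 0.765 with an estimated correlation), with psbC of photosystem II at -2.90 and the ribosomal protein gene rpl16 at 2.57; 0 passed over all genes or the list alone (limma; 38 at an unadjusted p under 0.05). Genes of ribosomal proteins had a median of -0.42 over 175 genes (camera adjusted p = 0.0315; adjusted p = 0.873 with an estimated correlation). AT3G47370, a ribosomal protein of the S10 family, passed at -2.91 (limma adjusted p = 0.00215), and AT3G09200 at -2.62 did not.

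These group differences rested on the comparison of ssRNase lists, and whether those of hair or of nonhair carried them was not tested. With dsRNase alone, a setting chosen after the data were seen, ribosomal proteins turned to 0.46 and passed camera toward hair, and chloroplast genes turned to 1.096 and did not pass. Camera used the preset correlation alone in this and every other setting but the fit as reported, where no list passed with the estimated one. The transfer RNA and photosynthesis groups then had fewer than 4 genes to test. Without nonhair replicate 1 or 2 the filter on lists with a PPS itself removed members seen only in nonhair, leaving 212 and 215 of 417 transfer RNA genes, 43 and 40 of 73 chloroplast genes and fewer than 4 photosynthesis genes. With that loss of members the transfer RNA call ended without nonhair replicate 1 (-0.13) and held without nonhair replicate 2 (-0.12), and the chloroplast call ended without either (-0.13 and -0.073). With the filter of all lists kept, a setting chosen after the data were seen, the transfer RNA (-0.96 and -0.88), photosynthesis (-1.78 and -2.02) and chloroplast groups (-0.87 and -0.84) passed camera without nonhair replicate 1 and 2. The ribosomal protein call was lost without hair replicate 2 (-0.21, and -0.20 with that filter) and, with that filter, without nonhair replicate 2 (-0.17).

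Genes of root hair growth did not separate the cell types as a group: 17 of 26 had a positive difference, median 0.67 (camera adjusted p = 0.235). ADF8 passed over all genes, and 5 genes toward hair and 3 toward nonhair passed when adjusted over the list alone. ACT8, an actin used in root hair growth, had a difference of -3.21 (limma adjusted p = 0.0562). Of 5 cell fate genes tested, none passed over all genes (limma, 0; 2 at an unadjusted p under 0.05), and 1 toward hair passed when adjusted over the list alone. GEM, a regulator of GL2 and CPC, had 2.92 (limma adjusted p = 0.0932), LRL1, a regulator of root hair development, 1.18, the receptor-like kinase SCM 0.63, and CPC, a MYB protein that moves into hair cells, -1.10. The cell fate median was 0.63 (camera adjusted p = 0.717), became -0.55 without hair replicate 2, and passed camera at 1.36 without hair replicate 1 and at 1.37 with dsRNase alone. The genes used to build the nuclear tag had a median of -0.68 and a mean of 0.062 over 4 genes (camera adjusted p = 0.319), with 1 gene in each direction past the list alone and ACT2 at -1.78. Phosphate starvation genes had a median of 0.26 and a mean of -0.029 over 25 genes (camera adjusted p = 0.836), and the median became -0.071 when lists were scaled to their total. In this group SPX3, with the losses named above, and MGD3, which makes galactolipids under low phosphate (-2.81, limma adjusted p = 0.0218; the same value without hair replicate 1 or 2, with the call lost), passed toward nonhair, and 1 further gene toward hair passed over the list alone.

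Genes for RNA-binding proteins had a median of 0.43 over 41 genes (camera adjusted p = 0.245), and 0 passed over all genes (limma; 17 at an unadjusted p under 0.05) and 1 toward hair when adjusted over the list alone. U2AF65A, which recognises the 3' splice site, had 780 ± 173 covered bases in hair and 158 ± 75.8 in nonhair (SD, n = 4; log2 difference 2.38, limma adjusted p = 0.05001, not below 0.05). The glycine-rich proteins GRP7 and GRP8 had -0.25 and 0.43, SE, which acts in microRNA processing, 0.62, CP29A, a chloroplast protein, -0.98, and UBP1C -1.77, none past the test. GRP7 turned to 0.070 without nonhair replicate 2, and CP29A to 1.45 with dsRNase alone. Housekeeping genes had a median of -0.77 over 9 genes (camera adjusted p = 0.0857), with 0 past over all genes (limma; 5 at an unadjusted p under 0.05), 1 toward nonhair when adjusted over the list alone, and the elongation factors EF1A-B and EF1A-C at -4.07 and -2.74. They passed camera at -0.56 without hair replicate 1. Genes of other root cell types had 0.97 over 9 genes (camera adjusted p = 0.414; 2.52 and past camera with dsRNase alone), with CASP1 of the endodermis at 1.504 and LHW of the vasculature at -1.47. Camera adjusted p was 0.892 for 91 lncRNA genes, where AT5G09415 passed toward hair (3.0005, SE 0.21) and AT2G33815 had 2.28. It was 0.589 for 4 rRNA genes, 0.401 for 268 snoRNA genes and 0.539 for 40 snRNA genes. The snoRNA group passed camera in opposite directions in other settings: toward nonhair without nonhair replicate 2 (median 0), though not with the filter of all lists kept, and toward hair with dsRNase alone (0.58 over 12 genes). Genes of tRNA, EF1A and LHCB1 have near-identical copies, and GL2, EF1A-C, AT3G09200, AT1G06397, AT3G08210, U2.14 and psbC overlap another gene on the same strand, so coverage of these is uncertain. The smallest p in the snoRNA group belonged to AT1G06397 (2.01) and AT3G08210 (-1.92), neither past the test. Scaling to the list totals moved the median of all genes from 0.048 to -0.073.

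Structure scores come from the libraries without protein. The deposited score is positive where more reads of one library and negative where more of the other were seen, and which sign means pairing was not settled. Inside PPS the score was lower than in the 50 nt on each side: the median difference was -0.58 over 24070 hair PPS and -0.55 over 32228 nonhair PPS. The score was lower inside for 69.5% of hair and 68.7% of nonhair PPS. Depth differed too: median reads per base were 16 inside and 6.9 in flanks in hair, and 23.6 and 14.6 in nonhair. A base with 1 read against 0 scores 1.27, so part of the gap may follow depth. With reads recovered from the scores and summed, a measure chosen after the data were seen, the medians were -0.43 in hair and -0.32 in nonhair. In coding sequence the medians were -0.63 and -0.61, and in introns -0.18 and -0.22. PPS found with dsRNase only had -0.47 in hair and -0.63 in nonhair, those found with ssRNase only -0.47 and -0.29, and those found with both -0.79 and -0.52. Intron PPS found with ssRNase only had 0.074 and 0.22. If PPS were called against the libraries without protein, the measures are coupled; how those libraries entered the caller is not given in the sources used here. With 1 pooled file per cell type there is no test between them.

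In both cell types the mean score at the start codon was below both sides, and at the stop codon it lay between a lower coding side and a higher 3' UTR side, with more contrast in nonhair. Upstream, at and downstream of the start codon it was 0.079, -0.037 and 0.0051 in hair and 0.17, -0.099 and 0.050 in nonhair. For the stop codon the values were -0.081, 0.038 and 0.089 in hair and -0.18, 0.22 and 0.27 in nonhair, so the score rose from coding sequence to 3' UTR, per mRNA by 0.14 in hair (SE 0.0171) and 0.43 in nonhair (SE 0.0165). Median reads per base fell there, from 13 to 6.36 in hair and from 19.9 to 12.5 in nonhair; with reads recovered from the scores and summed, a measure chosen after the data were seen, the rise was 0.22 and 0.41. With 10 nt on each side of it, the start codon lay below the rest of the window of 100 nt on each side by -0.081 in hair (SE 0.0165, 6670 mRNAs) and -0.21 in nonhair (SE 0.0165, 6963 mRNAs). At the stop codon it lay above by 0.025 in hair (SE 0.0149, 9733 mRNAs) and 0.19 in nonhair (SE 0.0140, 10366 mRNAs). The SE is over mRNAs, which are not replicates. With a window of 50 nt the hair stop codon turned to -0.012. When reads recovered from the scores were summed over mRNAs, the start codon had -0.042 and -0.13. A ratio per mRNA, tried before that, had 0.44 and 0.34, so the sign at the start codon rests on how reads are averaged.

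**Figure D3:**
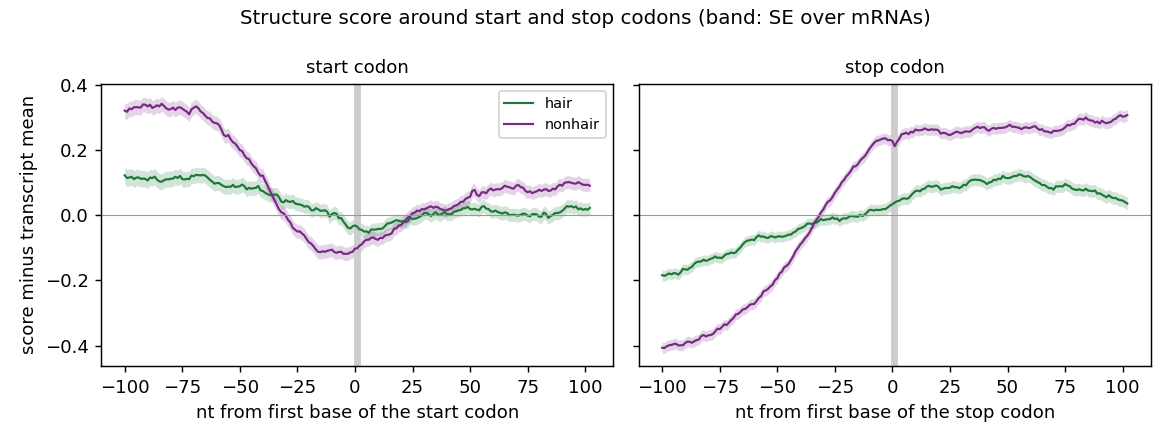
Mean structure score minus the transcript mean at each position within 100 nt of the start codon (left) and stop codon (right), hair in green and nonhair in purple, with bands for the SE over mRNAs. The nonhair curve dips at the start codon and rises across the stop codon, with a codon minus rest of window difference of -0.21 and 0.19.

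Transcripts of photosynthesis stood far apart in structure score. All 14 scored had a lower score in hair, with a median difference of -4.37, below each of 10000 random lists matched on mean score (percentile 0; median of the random lists 0.81). LHCA2 had -6.31, LHCB1.3 -5.92, the photosystem I subunit PSAF -5.62, LHCB3 -5.51, and FBA2, an aldolase of the Calvin cycle, -5.30. Scores were higher in hair for AT1G73510 (6.19), TAF4B, a subunit of the transcription factor TFIID (5.04), NOGC1 (4.70), PLP5, a patatin-like lipase (4.52), and AT4G24170 (4.41). Over 11437 transcripts the mean scores of the cell types had a Pearson r of 0.467 and a Spearman rho of 0.473 across transcripts, which are not replicates. The median difference was -0.26 and 63.3% were lower in hair. Among other groups, ribosomal protein transcripts had a median of -1.17 (percentile 0; median of the random lists -0.46), housekeeping -0.73 (0.23; 0.032), root hair growth -0.38 (0.98; 0.0093), nuclear tag genes -0.96 (1.52; -0.13), other root cell types -0.99 (3.6; -0.69), phosphate starvation -0.28 (20.1; -0.13) and cell fate genes -0.27 (58.6; -0.32). RNA-binding transcripts had -0.23, close to all transcripts, with 18 of 41 below the overall median; their percentile of 0.25 comes from matched random lists at 0.10. Scores of whole transcripts also follow their reads in each library. Ribosomal protein transcripts had 9432 CPM in the second nonhair library against 18406 to 18821 in the 3 others, and housekeeping ones 2446 in the second hair and 1264 in the second nonhair library. Summed over bases, the read depth of AT1G73510 was 722 and 16415 in the first and second nonhair libraries against 15131 and 4370 in hair. That of NOGC1 was 928 and 13240 against 5744 and 2154. TAF4B, PLP5 and AT4G24170 likewise had more depth in the second library than in the first in nonhair alone. There is 1 pooled file per cell type, so these differences have no replicate check. The median over all transcripts was -0.10 with medians in place of means per transcript.

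**Figure D4:**
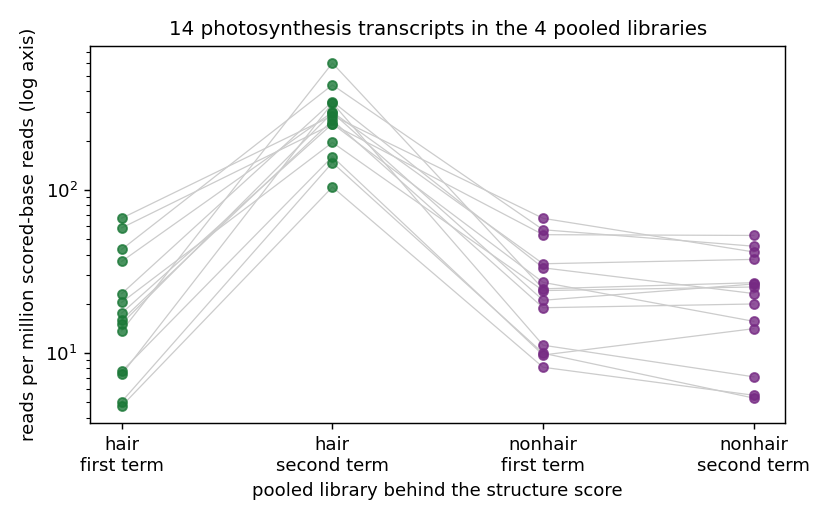
Scaled read depth (CPM, log axis) of 14 photosynthesis transcripts in the 4 pooled libraries behind the structure scores, with a line per transcript. Depth was recovered from the scores, summed over bases and scaled to a common library total. The second hair library holds 3978 CPM in sum, against 335, 399 and 345 in the others.

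At PPS specific to a cell type, the score inside the PPS was compared between cell types. Hair-specific PPS had a higher score in hair, with a median difference of 0.46 over 6946 PPS (bootstrap SE 0.0161). Nonhair-specific PPS had 0.056 over 12509 PPS (SE 0.0161), and shared PPS 0.53 over 19140 PPS (SE 0.00817). The median over all scored bases was -0.10. With 1 pooled file per cell type there is no test of these differences.

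Sequence motifs were counted in PPS against positions shuffled within the same kind of region of the same genes. GAA repeats, which purine-rich splicing enhancers contain, were more frequent in PPS in 8 of 8 lists, with a mean log2 ratio of 0.59. The ratio was 0.50 higher in hair than in nonhair (exact permutation p = 0.0556). CTT repeats were less frequent in 8 of 8 lists, mean -1.20, by -0.46 more in hair (exact permutation p = 0.0556). GGN repeats had a mean of 0.54 and were above the shuffled rate in 6 of 8 lists, with 1.12 and 1.11 in hair and nonhair with ssRNase and 0.29 and -0.36 with dsRNase (cell type difference 0.33, exact permutation p = 0.167). Means of the other motifs were 0.46 for G runs, 0.43 for TG repeats, 0.11 for RRACH, which m6A marking uses, 0.048 for the Pumilio site, -0.34 for the AU-rich pentamer, -0.57 for AT repeats and -0.88 for U runs. Against dinucleotide-shuffled PPS sequence, GAA stayed above at 0.99 and GGN at 1.25, while CTT turned to 0.40, AT to 0.97, G runs to -1.01 and TG to -0.25.

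**Figure D5:**
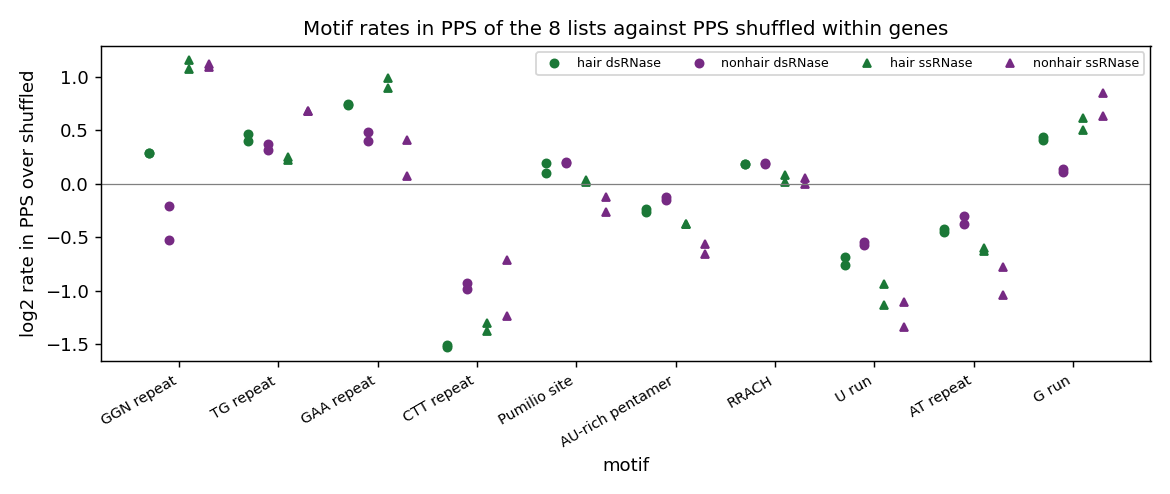
Log2 ratio of motif rates in PPS over PPS shuffled within genes, for 10 motifs in the 8 lists, with circles for dsRNase, triangles for ssRNase, green for hair and purple for nonhair. GAA repeats lie above 0 and CTT repeats below 0 in all 8 lists.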

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

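The tests of explanations given here, the count of other splits of the lists included, were chosen after the results they bear on had been seen.

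Photosynthesis transcripts had far lower structure scores in hair. In the second hair library behind the score their summed read depth was 9.97 times the highest of the 3 other libraries. LHCB1.3 stood at 597 and RCA at 439 CPM (read depth summed over bases, scaled to a common library total). RNA of green tissue in that library is therefore a candidate explanation, although nuclei were purified by their tag from excised roots. If PPS were called against it, it may also have lowered PPS coverage of these genes in hair, which was not tested. The gap in coverage lay mostly with ssRNase, 68 bases in hair against 1637.5 in nonhair, and was 34.5 against 81.5 with dsRNase. If each RNase was called against its own library, the second one would have to be the ssRNase library. The direction was left unsettled, and the values given for it leaned the other way. A change of pairing in hair cells allows at most 2.41 times, if the scaled reads of both libraries together stay the same for a transcript. That condition was not checked. Reads of these transcripts in the second hair library were 11.5 times those of nonhair, which argues against a change of pairing only under that condition. A shift of all scores between the files is argued against by a percentile of 0 among matched random lists. A difference between cell types in the amount of these transcripts was not tested apart from this; the first hair library, with 335 CPM against 399 in nonhair, did not show one.

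PPS of nonhair with ssRNase stood apart from the other lists, with a smaller coding share, larger intron and tRNA shares, and little overlap with dsRNase PPS of the same replicate. An exchange of lists as the sample descriptions place them is argued against by the 41402 PPS found under the RNase of their title. Another preparation of these libraries may be the cause: over 17 cold and osmotic stress genes the log2 ratio of the first to the second library was lower in nonhair than in hair by a median of -2.004 (16 of 17 lower), but by -0.52 among the 9 genes not seen before the list was written (8 lower); 35.3% of such genes had a PPS in these lists, not as few as this explanation had been taken to need, the design confounds preparation with cell type here, and which library had ssRNase was not settled. Fewer called sites were not settled as a cause. With ssRNase, nonhair lists held 11746.5 PPS on average against 12988 in hair. At the stricter score threshold the intron difference was -10.7 points, close to the -11.7 at the deposited one. It did not fall as far as this explanation had been taken to need. But that threshold cuts every list at its own median score, so it does not even out their numbers and cannot decide. A biological difference between hair and nonhair nuclei remains open and untested.

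PPS coverage of 178 genes differed between hair and nonhair. Of the 18 splits of the lists within RNase, 1, the real one, gave as many genes and the highest other gave 57, but with a smallest share of 5.56% the splits are too few for a share under 0.05. They also move the lists of a preparation separately, so this share is lower than whole preparations could give. Differences in transcript amount stay open: of 132 called genes with reads, 29.5% differed in the direction of the call by 2 times or more in the first or the second library (28 and 13 genes) and 13.6% by the mean of both, the form used first, which hides a difference in 1 library. By that mean 58 of 77 genes called for hair and 40 of 55 called for nonhair had reads in the direction of the call, 15 and 3 of them by 2 times or more. Of 6949 genes with reads that were not past the test, 3134 had more reads in hair, and 53 had at least 2 times as many. Genes called for hair therefore had more reads in hair more often than genes not past the test. Another preparation of the nonhair ssRNase libraries stays open, as does a biological difference: without those lists 123 of the 178 genes were called, but all had been chosen with these lists in the fit, a fault shared by the first form of this test (59.0% also called with dsRNase alone), and the number of genes called without them, used before, did not bear on the 178.

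For 1733 of 10196 genes the hair minus nonhair difference depended on the RNase (limma interaction), against 178 called for cell type. Nonhair ssRNase lists alone carry other internal replicate numbers, so this cannot be told apart from another preparation of those libraries. The fit took nonhair lists of the same replicate number as 1 preparation. Chloroplast-encoded genes had a log2 hair over nonhair ratio of covered bases of -0.64 with ssRNase and 1.05 with dsRNase, in every list the same way, and the difference was not tested. Genes of snoRNA had -0.12 with ssRNase and 1.73 with dsRNase, which was not tested either. The dsRNase value leaned on hair replicate 1, with 1803 covered bases against 657 in hair replicate 2 and 269 and 471 in nonhair. Mitochondrial PPS numbered on average 80 in hair and 50 in nonhair with dsRNase, and 205 and 400.5 with ssRNase. They are part of the numbers, lengths, covered length and overlaps of PPS, and were left out of regions, genes, structure scores and motifs.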

How the results depend on the processing

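Over 112 results and 1267 alternatives, 990 stayed the same, 54 reversed, 102 lost and 10 gained a call, and 111 moved. Tested results stayed the same if they kept direction and side of the threshold. Counts did so within a fixed fold of the reported one, and other values within their error. Chosen after seeing the data were dsRNase alone for all but gene counts and single genes, the fit without nonhair ssRNase lists, these as preparations of their own, the filter of all lists with a replicate left out, and recovered reads. Unless the setting itself changes the samples or genes used, the cause was not tested. Exact permutation tests of cell type cannot pass 0.05, so their p-values say nothing about stability. PPS depth is unknown; depth of the structure libraries limits scores at bases with 1 or few reads.

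Gene counts (hair and nonhair, 112 and 66 as reported) were 69 and 49 with a pseudocount of 1, 263 and 100 with 50, 170 and 100 scaled to list totals, 262 and 135 after quantile normalization, 71 and 46 without the preparation correlation, 544 and 592 with RNases averaged per preparation, 69 and 23 at the stricter score threshold (8053 genes; 39 calls kept, 1 with its sign turned), 390 and 510 with dsRNase alone (fewer samples), 1113 and 931 with ssRNase alone, 329 and 510 without the nonhair ssRNase lists, and 95 and 56 with these as preparations of their own (151 calls kept). With the nonhair lists exchanged they were 0 and 0 (limma, with 173 at an unadjusted p under 0.05). If titles hold, that setting mixes the RNases. Leaving out each replicate gave 128 to 298 and 93 to 203, with a lone list assumed to vary like the others. Named genes also lost their call (limma) with a pseudocount of 1 (AT2G31560, AT3G20370, SPX3, SQP2, WNK1) or 50 (MGD3), without the filter (SPX3, WNK1), with PPS numbers (SPX3), without the preparation correlation (AT1G64610, AT2G31560, AT5G44910, PTI1-4, SPX3, WNK1), with RNases averaged (AT2G31560, MGD3, SPX3, SQP2, WNK1), with ssRNase alone (AT2G31560, MGD3, PTI1-4, SPX3), with dsRNase alone (AT3G20370, CLPB4, NET4A, SQP2, WNK1), without the nonhair ssRNase lists (AT3G20370, SPX3, SQP2, WNK1), with these as preparations of their own (SPX3, WNK1), with the nonhair lists exchanged (all 24 named as past the test) and at the stricter score threshold (AT1G64610, AT1G73510, AT3G47370, AT3G54040, AT5G12410, AT5G44910, CLPB4, CT-BMY, HDA9, NET4A, PTI1-4, SPX3, WDL1, WNK1; MGD3 had no value there).

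With the replicate number as a block the counts were 571 and 275, and all 178 calls were kept; no list changed its call under the block. Deviations of same-numbered hair and nonhair lists correlated at 0.0324 with dsRNase and -0.00084 with ssRNase. But hair lists of the same number, whose lysate was split between the RNases per the labels, correlated at only 0.0172. Such a correlation therefore cannot show whether the numbers pair the samples.

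With each replicate left out, ranges were -2418 to 1418 for the difference in PPS number, -165 to 356 kb for covered length, -0.0280 to 0.0540 points for 5' UTRs between RNases, and -0.57 to 0.070 for GRP7. List medians ranged from -1.17 to -0.073 for chloroplast genes, -0.55 to 1.36 for cell fate, -1.10 to -0.38 for housekeeping, -0.040 to 0.0051 for lncRNA, -0.033 to 0.39 for phosphate starvation, -0.73 to -0.15 for ribosomal proteins, -0.00396 to 0 for snoRNA and -1.15 to -0.12 for tRNA. The tRNA call ended without nonhair replicate 1 and the chloroplast call without nonhair replicate 1 or 2, where fewer genes were tested, and the ribosomal protein call without hair replicate 2. With the filter of all lists kept, cell fate genes were 0.57 without nonhair replicate 1, with camera's direction reversed, and lncRNA genes -0.0049 and -0.046 without hair replicate 1 and nonhair replicate 1. Without nonhair replicate 2 snoRNA genes passed camera toward nonhair, but not with that filter. Hair minus nonhair motif ratios ranged from -0.0065 to 0.025 for RRACH and -0.058 to 0.078 for U runs.

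With an estimated correlation, camera lost its calls for tRNA (-0.87), photosynthesis (-1.87), chloroplast (-0.84) and ribosomal proteins (-0.42), and its direction for nuclear tag genes (-0.68), with medians as reported. With dsRNase alone list medians were 1.096 for chloroplast, 0.46 for ribosomal proteins, 0.58 for snoRNA (past camera), -0.026 for snRNA, 0.077 for phosphate starvation, 1.37 for cell fate and 2.52 for other root cell types; photosynthesis, tRNA, rRNA and nuclear tag genes had fewer than 4 members and no value. CP29A was 1.45 there and without the nonhair ssRNase lists. Covered length became -146 kb, 5' UTRs 0.00973 and non-coding RNA 0.0384 points, and hair minus nonhair motif ratios -0.096 for AT repeats, -0.11 for the AU-rich pentamer, -0.051 for Pumilio, -0.00080 for RRACH, 0.089 for TG repeats and -0.17 for U runs. Scaling to list totals gave snRNA -0.35 and snoRNA -0.34, both past camera. With nonhair lists exchanged housekeeping passed at -0.77. With PPS numbers in place of bases SE was -0.10.

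The stricter score threshold gave -1.41 for SE, -0.105 points for 5' UTRs between RNases, -0.036 for the Pumilio difference, 60.8% and 48.8% of merged PPS shared, 11878 nonhair-specific PPS, and overlaps of 44.9% between cell types with dsRNase, 54.6% between replicates with dsRNase and 55.6% with ssRNase. With introns placed first, 5' UTRs were 0.341 points higher in hair. A reciprocal overlap of 50% gave 53.5% and 41.6% shared, 16002 hair-specific PPS, 42.2% and 19.5% between cell types (dsRNase and ssRNase), 53.5% and 44.1% between replicates, 15.3% between RNases, and 0.51 and 0.20 for score differences inside hair-specific and nonhair-specific PPS. Counting overlaps of 50% of the first PPS gave 48.6%, 25.3% and 48.7% (cell types with dsRNase and ssRNase, replicates with ssRNase). Within 50 nt 76.6% and 63.2% were shared. PPS found in both replicates were shared at 53.8% and 52.8%, with 8524 specific to nonhair. The exchange gave 39.5% between cell types and 45.0% between replicates with dsRNase, 39.1% with ssRNase, and 50.5% between RNases.

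Score differences inside minus flank, given for all, dsRNase-only and ssRNase-only PPS, were -0.50, -0.40 and -0.37 in hair and -0.45, -0.54 and -0.19 in nonhair with 25 nt flanks. With 100 nt they were -0.52 for hair ssRNase-only and -0.60, -0.68 and -0.37 in nonhair. With PPS found in both replicates they were -0.71, -0.56 and -0.68 in hair and -0.59, -0.70 and -0.38 in nonhair. With the spliced file they were -0.40, -0.28 and -0.53 in hair and -0.32, -0.31 and -0.40 in nonhair. With recovered reads they were -0.43, -0.33 and -0.35 in hair and -0.32, -0.37 and -0.16 in nonhair. Means in place of medians gave -0.67 and -0.20 for nonhair dsRNase-only and ssRNase-only, and 0.55 inside shared PPS.

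At codons, windows at least 90% scored gave -0.13 (hair) and -0.26 (nonhair) at the start. A window of 50 nt gave -0.093 at the nonhair start and -0.012 and 0.099 at the stop. Summed reads gave -0.042 and -0.13 at the start and 0.077 and 0.24 at the stop, 0.22 for the hair rise across the stop codon, and the ratio per mRNA 0.44 and 0.34, and 0.67 and 0.91. The transcript correlation was 0.431 and the median difference -0.29 with the unspliced file, and 0.533 and -0.14 with recovered reads, which also gave 0.39, 0.016 and 0.41 inside hair-specific, nonhair-specific and shared PPS. With medians per transcript the difference was -0.10.

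Against dinucleotide-shuffled sequence, mean motif ratios were 0.97 for AT, 0.40 for CTT, -1.01 for G runs, 0.99 for GAA, 1.25 for GGN, 0.72 for Pumilio, 0.0087 for RRACH, -0.25 for TG and -0.34 for U runs, and hair minus nonhair -0.041 for AT, 0.082 for CTT, -0.036 for RRACH and -0.029 for U runs. Shuffled over the whole gene, means were -0.98 for AT, -0.66 for the AU-rich pentamer, -0.43 for Pumilio, 0.24 for TG and -1.42 for U runs, and hair minus nonhair -0.26, -0.18 and -0.14 for AT, AU-rich and Pumilio and -0.41 for U runs.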

Other observations

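The genes whose promoters drive the nuclear tag were also seen in the libraries behind the structure scores, which hold no protein. GL2 had 70.3 and 71.8 CPM (read depth summed over bases, scaled to a common library total) in the first and second nonhair libraries, against 25.9 and 34.3 in hair. ADF8 had 27.0 and 43.8 in hair against 20.6 and 17.4 in nonhair. Each library pools replicates, so these values have no replicate check.

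Of 22 genes that respond to cold and osmotic stress, 16 had a PPS with dsRNase in hair and 16 in nonhair, and 14 in hair and 6 in nonhair with ssRNase; the list was written after part of it had been seen, and the genes named from it were chosen after their values were seen. With dsRNase, LTI78, a dehydration-responsive protein, had 1152 covered bases in hair and 221 in nonhair on average. With ssRNase it had 541 in hair and 0 in nonhair. SRO5 had 594 and 361 with dsRNase and 344.5 and 28.5 with ssRNase. COR47, a dehydrin, had 804 in hair and 186.5 in nonhair with ssRNase. Of 17 genes with PPS in nonhair dsRNase lists or with both RNases in hair, 6 had a PPS in a nonhair ssRNase list (35.3%) and 14 in a hair ssRNase list. CT-BMY, named among the genes higher in hair, is on this list. These values have no test of their own.

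Reads of 11437 transcripts ranked alike in the first and second hair libraries (Spearman 0.908) and less so in the nonhair ones (0.769), across transcripts, which are not replicates. In nonhair, 186 transcripts were more than 4-fold lower in the first library than in the second and 46 higher. In hair these numbers were 55 and 4.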
